A study of Homo sapiens with 70 samples.

How the data were processed

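Total RNA from 70 samples of human skin, nevi and melanomas was measured on oligonucleotide arrays, 1 array per sample. The deposited values are probe set signal intensities on a linear scale, made by the authors with MAS5 (no version given), which the submitters' processing notes name. The deposited values show how they were scaled: all lie between 0.1 and 158864.8, and the mean without the lowest and highest 2% of probe sets was 600.2 on every array. The table held 22283 probe sets in 70 columns, and no column was left out. Samples were grouped by the tissue that each label names, which gave 7 normal skin, 18 nevus and 45 melanoma arrays. Replicate numbers follow the order of deposit and pair nothing. Labels name no batch, pairing or covariate. RNA was isolated with 1 of 2 protocols, Trizol or RNeasy, and the labels do not say which was used for which sample.

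Probe sets were joined to genes by the annotation that came with the array. Of the 22283 probe sets 68 were controls, 19065 had 1 gene symbol, 1043 had several and 2107 had none. A reference gene table was used for symbols and chromosomes only, with no coordinates: 19053 of the 19065 probe sets matched it by gene identifier, and 0 symbols needed an update. The 31 probe sets of XIST and of genes on the Y chromosome were left out, which left 11939 distinct genes. A gene was tested when its probe set lay above the median of its own array on at least 7 of the 70 arrays. Of several probe sets of a gene, that with the highest mean over all arrays was kept. This gave 9092 tested genes.

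Signals were taken as log2 of the deposited value plus 50, so each fold change given is one of this sum and understates changes in genes of low signal, where the signal floor limits what can be seen. A linear model with a mean per group was fitted to all 70 arrays with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with eBayes and an intensity trend. Melanoma was compared with nevus, melanoma with normal skin, and nevus with normal skin. A gene passed the threshold at a Benjamini-Hochberg adjusted p under 0.05, over all tested genes, and a log2 difference of at least 1 in size. Each adjusted p of a gene comes from limma. Genes past the threshold in the same direction in a pair of comparisons were counted. As these comparisons share arrays, the counts stand beside the product expected of independent lists, 100 simulations with no differences, and a split of the shared arrays (22 and 23 melanomas, 3 and 4 normal skin arrays).

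In all, 36 gene lists of cell types, pathways and complexes were fixed from general knowledge. The first 12 lists were melanocyte lineage and pigment, melanoma-associated, cancer-testis antigens, basal keratinocyte, cornified envelope, epithelial junction, wound-type keratinocyte, sweat gland, hair follicle, fibroblast and dermal matrix, matrix remodelling and endothelial. The next 12 were smooth muscle, skeletal muscle, adipocyte, Schwann cell, T cell, cytotoxic and NK cell, B cell and plasma cell, macrophage, Langerhans and dendritic cell, mast cell, red blood cell and cell cycle. The last 12 were interferon response, MHC class I presentation, MHC class II presentation, immediate early, MAPK pathway output, p53 targets, unfolded protein and integrated stress response, hypoxia, glycolysis, oxidative phosphorylation, ribosomal protein, cholesterol and fatty acid synthesis. For each list the measured members past the threshold were counted, adjusted over all genes and over the list alone. Lists were tested with camera of limma with the correlation between genes estimated, adjusted over the 36 lists, and again with a preset correlation of 0.01. The genes named were those of a fixed rule: the 8 largest rises and the 8 largest falls past the threshold of each comparison, up to 3 members of each list with the largest differences past the threshold or, where none passed, that with the smallest p, the 10 genes with the largest smaller-of-2 differences of each shared count, and GDF15, L1CAM, PMEL and TYR. The text prints part of them. The comparisons, tests, lists, rule for named genes and all alternatives but 4 were fixed before the data were examined. Scores were planned over all 45 melanomas, and were correlated within the group of like arrays once these were seen to fall into separate groups.

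RNA quality was read from the log2 ratio of the 3' to the 5' control probe sets of GAPDH and ACTB, each signal plus 50, and compared between groups with exact two-sided rank-sum tests, or with 100000 permutations where values were tied. These 9 tests were adjusted together. Nevi with a GAPDH log2 ratio above 2 are called high-ratio nevi. Likeness of arrays was measured by the Pearson correlation of log2 signals across genes, which are not independent replicates, and arrays were joined by average linkage at correlations above 0.9. This level and the ratio limit of 2 were set after the data were seen. Scores of lists were means of standardised log2 values.

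The alternatives were a pseudocount of 10 or 200, quantile normalization, centring on the median of the tested genes, no filter on dim probe sets, a filter at the 75th percentile, the mean of the probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, a spread per group, a fit of only the 2 groups compared, eBayes without trend, a keratinocyte score or the 3'/5' ratio as a covariate, each normal skin array left out in turn, no limit on the size of the difference, and the preset correlation. Chosen after the data were seen were a fit without the 3 high-ratio nevi, a fit of these 3 nevi alone against normal skin, averaged like arrays, and a fit without nevus 3 and melanoma 14, whose median correlations with their own groups were 0.815 and 0.827 and whose TYR signal lay below or within that of normal skin. Nevus 17, a high-ratio nevus, had a lower median correlation (0.775) and TYR within normal skin (9.33), and was kept in this last fit.

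The steps were tested on data with known changes, made from the residuals of the 9092 genes after the group means were taken away, with the arrays shuffled over the groups. Changes were added to 200 genes drawn at random, 50 at each of 4 sizes. Of the genes changed 2-fold, 46% passed in melanoma against nevus, 62% in melanoma against normal skin and 48% in nevus against normal skin. At 3-fold the shares were 100%, 96% and 94%, and at 4-fold and 8-fold 100% each. Of the unchanged genes 0, 55 and 0 passed. A list of 20 genes raised 2-fold passed, and 0 of the 35 other lists did. Files were read with python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Depth on an array is set by signal over background, and the share of probe sets above a signal of 200 was 55.1% ± 2.1 (SD, n = 45) in melanomas, 57.5% ± 2.16 (SD, n = 18) in nevi and 58.8% ± 2.92 (SD, n = 7) in normal skin.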

Results

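RNA from 70 human tissue samples was measured on 1 oligonucleotide array each. The samples were 7 of normal skin, 18 of nevi, the benign growths of melanocytes known as moles, and 45 of melanoma, the malignant tumour of the same cell type. Each array gave a signal for 22283 probe sets. The labels do not say whether the samples came from separate people, so each p-value given here measures only the spread between these samples. The number of arrays, with 7 in the smallest group, limited the precision. The median signal of an array was 243.3 in melanomas (range 207.6 to 299.5), 265.25 in nevi (247.0 to 321.2) and 265.9 in normal skin (256.9 to 344.6). It was lower in melanomas than in nevi (two-sided permutation rank-sum test, adjusted p = 3.0e-05 over 9 tests, from the smallest p that 100000 permutations can give) and than in normal skin (adjusted p = 0.000607), while nevi and normal skin did not differ past the threshold (adjusted p = 0.484).

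The log2 ratio of the 3' to the 5' control probe sets of GAPDH, which is higher where RNA is shortened, parted the groups. It was 4.71 ± 1.26 (mean ± SD, n = 7) in normal skin, 1.12 ± 1.89 (n = 18) in nevi and 0.49 ± 0.47 (n = 45) in melanomas. Every normal skin array lay above every melanoma array (exact two-sided rank-sum test, adjusted p = 6.73e-08), and normal skin lay above nevi (exact test, adjusted p = 0.00184). Melanomas and nevi did not differ past the threshold (exact test, adjusted p = 0.994). Nevus 12, nevus 15 and nevus 17 had log2 ratios of 6.02, 4.82 and 4.54, within the range of normal skin, and are called high-ratio nevi here. The ACTB control probe sets gave adjusted p = 6.73e-08 for melanoma against normal skin, 0.0027 for nevi against normal skin and 0.377 for melanoma against nevi in the same exact test.

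**Figure D1:**
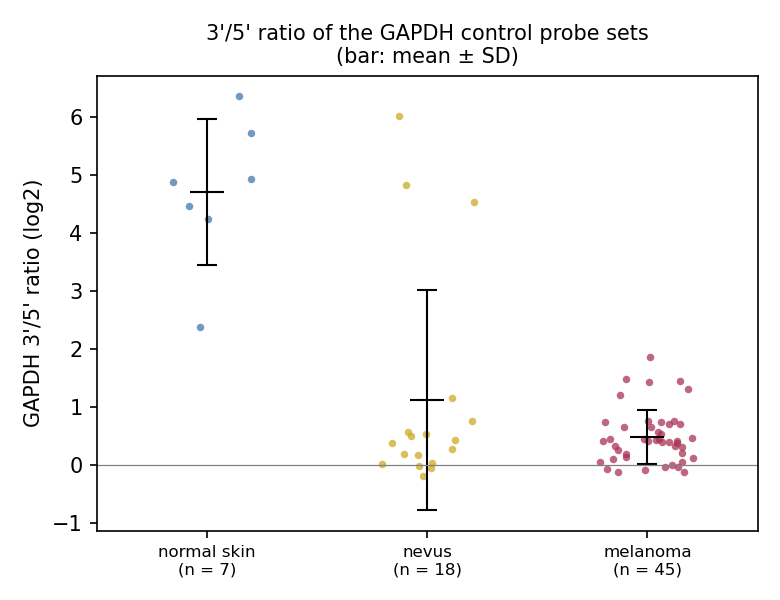
Log2 3'/5' ratio of the GAPDH control probe sets (y axis, log2 units, no transformation beyond log2) on each of the 7 normal skin, 18 nevus and 45 melanoma arrays (points), with the mean and SD of each group (bars). The 7 normal skin arrays lie between 2.38 and 6.35, 3 nevi lie between 4.54 and 6.02, and no melanoma lies above 1.87.

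Arrays of a group were not equally alike. The median correlation of log2 signals between pairs of arrays was 0.916 in melanomas, 0.856 in nevi (0.884 without the high-ratio nevi) and 0.866 in normal skin. Of the 45 melanomas, 35 joined a single group of like arrays at correlations above 0.9, with a median pair correlation of 0.934, which follows in part from how they were picked. Averaging all arrays so joined left 10 melanoma, 8 nevus and 6 normal skin samples, and each count was fitted again on these samples as an alternative chosen after the data were seen, called averaged arrays below. In this fit the 35 like melanomas count as a single sample of the 10, and the melanomas outside that group carry most of the weight. A call that ended there therefore does not show that the difference was absent among the 35. Pigment markers of some arrays went against their labels. The array labelled nevus 3 had log2 signals of 8.46 for PMEL and 8.25 for TYR, below every normal skin array (8.81 to 9.83 and 8.37 to 9.36). In 2 more nevi PMEL, and in 2 TYR, lay no higher than in the highest normal skin array. The array labelled melanoma 14 had TYR at 8.96, within normal skin, PMEL at 10.22 and the highest skeletal muscle score of all 70 arrays (4.37). All were kept under their labels. Without nevus 3 and melanoma 14, an alternative chosen after the data were seen, 540 genes were higher and 803 lower in melanomas than in nevi, 1049 and 1380 in melanomas than in normal skin, and 524 and 590 in nevi than in normal skin.

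The comparison of 45 melanomas with 18 nevi addressed the question in the title of the series, which genes belong to malignant and not to benign growths of melanocytes. GDF15, which encodes a secreted stress cytokine, was 22.1-fold higher in melanomas (log2 difference 4.47 ± 0.24 SE, adjusted p = 8.61e-26; chromosome 19), with a mean log2 signal of 12.16 ± 0.83 (SD, n = 45) against 7.69 ± 0.78 (SD, n = 18). It lay above every nevus and every normal skin array in 44 of the 45 melanomas. L1CAM, a cell adhesion molecule first known from neurons, was 10.5-fold higher (3.39 ± 0.40 SE, adjusted p = 2.13e-11; chromosome X), with 12.58 ± 1.66 against 9.19 ± 1.11, and lay above all benign samples in 37 melanomas. The remaining melanomas had L1CAM between 7.59 and 10.73, within the benign range, and none of them was among the 35 like arrays. KRT14, a keratin of basal keratinocytes, was 119-fold lower in melanomas (-6.90 ± 0.64 SE, adjusted p = 4.81e-15), with 8.54 ± 2.85 against 15.44 ± 1.05, and lay below all benign samples in 38 melanomas. It fell into 2 sets: those 38 lay between 5.94 and 9.06, and the other melanomas between 13.85 and 15.33. The mean and the fold change mix both sets. The study singled out GDF15 and L1CAM on these samples, as far as is known, so their rise here is not independent evidence.

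Past the threshold, 508 of 9092 genes were higher and 768 were lower in melanomas than in nevi. The 8 largest rises also held WFDC1 (4.19 ± 0.46 on the log2 scale, SE), PHACTR1 (3.92 ± 0.21), SPP1, which encodes osteopontin (3.87 ± 0.31), the neurotrophin receptor NTRK3 (3.69 ± 0.44), ATP6V0E2 (3.48 ± 0.27) and the intermediate filament NES (3.44 ± 0.31). NES was 2.59 lower in the high-ratio nevi than in the other 15 nevi (log2 difference -2.59). The other 7 of the 8 largest falls were KRT15 (-6.52), KRT1 (-6.52), the cornified envelope protein LORICRIN (-6.41), KRT5 (-6.20), the water channel AQP3 (-5.46), FGFR3 (-5.44) and HOPX (-5.33).

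Of 22 measured genes of melanocyte lineage and pigment 11 rose, 1 fell and 10 did not pass (adjusted p = 0.562 with an estimated correlation). Examples were the melanosome receptor GPR143 (2.98 ± 0.36 SE), the apoptosis inhibitor BCL2A1 (2.76 ± 0.16) and the melanosome matrix protein PMEL (2.70 ± 0.30, adjusted p = 4.87e-12; chromosome 12), whose mean log2 signal was 14.78 ± 0.86 against 12.08 ± 1.71. TYR, tyrosinase, the first enzyme of melanin synthesis, was 4.27-fold higher (2.09 ± 0.32, adjusted p = 6.89e-08; chromosome 11), with 14.34 ± 0.97 against 12.24 ± 1.79. The member that fell was OCA2 (-1.65), named after its values were seen. The list's median was lower in the high-ratio nevi than in the other nevi (-0.54), with PMEL at -2.20, GPR143 at -1.82, TYR at -0.80 and BCL2A1 at -0.06. Of 17 measured melanoma-associated genes, a list that holds GDF15 and L1CAM and is therefore not independent evidence of its direction, 7 rose and 10 did not pass (adjusted p = 0.0649 with an estimated correlation). Without the high-ratio nevi 9 of these genes rose and 1 fell.

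Of 18 measured genes of the cornified envelope 17 fell (adjusted p = 0.287 with an estimated correlation), among them KRT1, LORICRIN and FLG (-4.91). Of 14 genes of epithelial junctions 11 fell (adjusted p = 0.287 with an estimated correlation), among them desmoplakin, DSP (-5.32), PKP1 (-5.27) and SERPINB5 (-5.09). Of 11 basal keratinocyte genes 7 fell and 1 rose (adjusted p = 0.287 with an estimated correlation), the P-cadherin gene CDH3 (2.24), named after its values were seen. Of 7 genes of wound-type keratinocytes 6 fell (adjusted p = 0.562 with an estimated correlation), with S100A7 at -4.93 and S100A8 at -2.70. Of 7 hair follicle genes 6 fell, with GATA3 at -4.45 (adjusted p = 0.287 with an estimated correlation), and this list's median was 1.83 higher in the high-ratio nevi than in the other nevi. Of 7 genes of Langerhans and dendritic cells, which reside in the epidermis and dermis, 5 fell (adjusted p = 0.287 with an estimated correlation), with the IgE receptor chain FCER1A at -2.25, the langerin gene CD207 at -2.22 and CD1C at -1.84.

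Of 39 measured cell cycle genes 16 rose and 23 did not pass (adjusted p = 0.287 with an estimated correlation), with CKS2 at 1.74 ± 0.18 (SE), PTTG1 at 1.63 ± 0.13 and KIF20A at 1.59 ± 0.19. Of 16 genes of matrix remodelling 9 rose (adjusted p = 0.367 with an estimated correlation), with the collagenase MMP1 at 3.10 and the basement membrane collagens COL4A2 at 1.98 and COL4A1 at 1.93. Of 16 glycolysis genes 6 rose and 1 fell (adjusted p = 0.287 with an estimated correlation), with PKM at 2.67, ENO2 at 2.36 and GPI at 2.24. PKM was lower in the high-ratio nevi than in the other nevi (-3.42), and without these 3 nevi 3 glycolysis genes rose. Of 17 fibroblast and dermal matrix genes 2 rose and 5 fell, with DPT at -1.92 and DCN at -1.63. Of 11 genes of MHC class II presentation 7 fell, with HLA-DPA1 at -1.70, HLA-DQA1 at -1.66 and HLA-DRB1 at -1.48 (adjusted p = 0.845 with an estimated correlation). Adjusted over the list alone, every count of this comparison was the same as that over all genes. No list passed camera with an estimated correlation; 5 of the 36 lists had an unadjusted p under 0.05, and 14 passed with a preset correlation of 0.01.

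With averaged arrays 323 genes were higher and 488 lower, and the calls of WFDC1 (0.93), NTRK3 (0.52), L1CAM (1.18), TYR (2.02), OCA2 (-0.16), CDH3 (1.34), S100A7 (-2.60), S100A8 (-1.95), DCN (-0.88), COL4A2 (1.19), COL4A1 (1.11), CD207 (-0.98), PTTG1 (0.94), KIF20A (0.94), HLA-DQA1 (-0.27), HLA-DPA1 (0.02) and HLA-DRB1 (0.42) ended. With the keratinocyte score as a covariate, which is built from these same keratins and takes away real differences too, 301 genes were higher and 266 lower, and the calls of KRT14 (-1.08), LORICRIN (-1.36), KRT5 (-0.46), FLG (-0.55), DSP (-0.98), PKP1 (-0.33), S100A7 (1.14), S100A8 (0.93), OCA2 (-0.38), DCN (-0.66), CD207 (-0.57), HLA-DPA1 (-0.60), HLA-DQA1 (-0.82) and HLA-DRB1 (-0.20) ended.

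The comparison of 45 melanomas with 7 normal skin samples had the largest counts of the 3 comparisons, and no list passed camera in it with an estimated correlation. GPR143 was 56.6-fold higher in melanomas (log2 difference 5.82 ± 0.53 SE, adjusted p = 3.91e-15), with a mean log2 signal of 12.24 ± 1.29 (SD, n = 45) against 6.42 ± 0.11 (SD, n = 7). PMEL was 48.1-fold higher (5.59 ± 0.44 SE, adjusted p = 1.01e-17) and TYR 41-fold higher (5.36 ± 0.47 SE, adjusted p = 1.07e-15). SCGB2A2, a secretoglobin of sweat and mammary glands, was 195-fold lower (-7.61 ± 0.60 SE, adjusted p = 1.01e-17), with 7.05 ± 1.41 against 14.65 ± 0.50. GDF15 was 23.1-fold higher (4.53 ± 0.34 SE, adjusted p = 2.5e-18) and L1CAM 8.23-fold higher (3.04 ± 0.58 SE, adjusted p = 6.15e-06).

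Past the threshold, 1033 genes were higher and 1366 lower in melanomas than in normal skin. The other 5 of the 8 largest rises were the lipase ABHD2 (5.11), the phosphatase DUSP4 (5.06), the spindle checkpoint gene MAD1L1 (5.05), SDC3 (4.81) and the ubiquitin-conjugating enzyme UBE2S (4.74). In the high-ratio nevi minus the other nevi these 5 genes had log2 differences of -1.75, -2.12, -3.09, -2.28 and -2.67. The other 7 of the 8 largest falls were SCGB1D2 (-7.53), KRT14 (-7.41), KRT15 (-6.31), the fatty acid carrier FABP4 (-6.30), PIP (-6.13), LORICRIN (-6.08) and the adipocyte protease CFD (-6.01).

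Of 22 pigment and melanocyte lineage genes 19 rose and 3 did not pass (adjusted p = 0.192 with an estimated correlation). Of 17 melanoma-associated genes 8 rose, with NES at 3.91 and SPP1 at 3.29, and 1 fell (adjusted p = 0.169 with an estimated correlation), in a list that is not independent evidence. Of 39 cell cycle genes 22 rose (adjusted p = 0.242 with an estimated correlation), with TYMS at 2.38, TPX2 at 2.11 and KIF20A at 2.09. Of 16 glycolysis genes 7 rose and 1 fell (adjusted p = 0.403 with an estimated correlation), with PKM at 3.58, GPI at 3.02 and ENO2 at 2.48. These 3 genes had log2 differences of -3.42, -1.99 and -1.98 in the high-ratio nevi minus the other nevi. Of 13 genes of MAPK pathway output 5 rose, with DUSP4 and ETV5 (3.25), and 2 fell. The median of this list was -0.77 in the high-ratio nevi minus the other nevi. Of 12 genes of MHC class I presentation 4 rose, with the immunoproteasome subunit PSMB8 at 1.59, and 1 fell. PSMB8 had a log2 difference of -2.69 in the high-ratio nevi minus the other nevi, and with the 3'/5' ratio as a covariate no MHC class I gene rose and PSMB8 stood at -0.62.

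All 9 smooth muscle genes fell (adjusted p = 0.252 with an estimated correlation), with MYH11 at -5.82 and LMOD1 at -3.95, as did all 6 adipocyte genes, with ADIPOQ at -4.43 (adjusted p = 0.192 with an estimated correlation), and 6 of 7 sweat gland genes (adjusted p = 0.100 with an estimated correlation). Of 10 endothelial genes 7 fell (adjusted p = 0.403 with an estimated correlation), with CLDN5 at -3.54 and PECAM1 at -3.27. Of 17 fibroblast and dermal matrix genes 11 fell (adjusted p = 0.558 with an estimated correlation), with FBLN2 at -3.74 and PDGFRA at -3.30. Of 11 basal keratinocyte genes 9 fell and 1 rose (adjusted p = 0.403 with an estimated correlation), of 18 cornified envelope genes 14 fell (adjusted p = 0.58 with an estimated correlation), and of 14 epithelial junction genes 12 fell, with DSP at -5.73 (adjusted p = 0.493 with an estimated correlation). All 5 mast cell genes fell, with the carboxypeptidase CPA3 at -2.78 (adjusted p = 0.493 with an estimated correlation), and 6 of 7 Langerhans and dendritic cell genes, with FCER1A at -2.61 (adjusted p = 0.403 with an estimated correlation). Of 18 immediate early genes 10 fell (adjusted p = 0.493 with an estimated correlation), with KLF4 at -4.66, FOSB at -4.34 and DUSP1 at -4.13. Of 11 MHC class II genes 6 fell, with HLA-DPA1 at -2.40 (adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, these counts were the same. No list passed camera with an estimated correlation; 6 of the 36 lists had an unadjusted p under 0.05, and 16 passed with a preset correlation of 0.01.

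The 3'/5' ratio of no melanoma reached that of any normal skin array, so the ratio and the 2 groups could not be parted within this comparison. With the ratio as a covariate in the model of all 70 arrays 811 genes were higher and 1190 lower, and of the 1033 and 1366 genes first called 474 and 918 were kept. Centring each array on its median moved the median difference of all genes from -0.12 to 0.04 and the counts to 1292 higher and 1112 lower, and with averaged arrays the calls of L1CAM (1.08) and HLA-DPA1 (-0.21) ended, as did that of HLA-DPA1 (-1.44) with the keratinocyte score as a covariate. With that covariate the calls of NTRK3 (1.74), KRT5 (-0.91) and KRT1 (-0.85) ended too.

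The comparison of 18 nevi with 7 normal skin samples set benign growths of melanocytes against skin, in groups that also differed in the 3'/5' ratio. MLANA, the melanocyte antigen also known as MART-1, was 19.6-fold higher in nevi (log2 difference 4.29 ± 0.57 SE, adjusted p = 1.3e-08), with a mean log2 signal of 13.40 ± 2.09 (SD, n = 18) against 9.10 ± 0.54 (SD, n = 7). TYR was 9.60-fold higher (3.26 ± 0.52 SE, adjusted p = 9.48e-07) and PMEL 7.39-fold higher (2.89 ± 0.48 SE, adjusted p = 2.77e-06). SCGB2A2 was 177-fold lower (-7.47 ± 0.66 SE, adjusted p = 1.66e-14), with 7.18 ± 1.97 against 14.65 ± 0.50. GDF15 (0.06 ± 0.38 SE, adjusted p = 0.912) and L1CAM (-0.35 ± 0.63 SE, adjusted p = 0.7) did not pass.

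Past the threshold, 510 genes were higher and 551 lower in nevi than in normal skin. The 8 largest rises also held the melanocyte channel gene TRPM1 (3.83), the translation factor EIF2S3 (3.49), TMEM259 (3.17), S100A7 (3.07), the semaphorin receptor PLXNB1 (2.98) and GAPDHS (2.95). EIF2S3 and TMEM259 lay above every normal skin array in all 18 nevi, and EIF2S3, TMEM259, PLXNB1 and GAPDHS had log2 differences of -2.46, -2.02, -3.48 and -2.03 in the high-ratio nevi minus the other nevi. The other 7 of the 8 largest falls were SCGB1D2 (-7.11), PIP (-5.69), FABP4 (-5.18), MYH11 (-4.78), the retinol carrier RBP4 (-3.71), G0S2 (-3.65) and LMOD1 (-3.60).

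Of 22 pigment and melanocyte lineage genes 14 rose and 8 did not pass, and 15 rose adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). Markers of glands, muscle, fat and vessels fell: 5 of 7 sweat gland genes (adjusted p = 0.0159 with an estimated correlation), all 9 smooth muscle genes, 5 of 6 adipocyte genes, with PLIN1 at -3.50, and 7 of 10 endothelial genes, with PECAM1 at -3.26, CLDN5 at -3.03 and VWF at -2.49. The smooth muscle, adipocyte and endothelial lists each had adjusted p = 0.158 with an estimated correlation. Of 17 fibroblast and dermal matrix genes 12 fell, with FBLN2 at -2.70, and of 16 matrix remodelling genes 8 fell, with COL4A1 at -2.54 (adjusted p = 0.622 for each, with an estimated correlation). Of 18 immediate early genes 10 fell, with CCN1 at -3.13, FOSB at -2.74 and DUSP1 at -2.07 (adjusted p = 0.532 with an estimated correlation). Of 13 genes of MAPK pathway output 4 rose and 1 fell, with ETV5 at 2.45 and DUSP4 at 2.07 (adjusted p = 0.407 with an estimated correlation). The median of this list against normal skin was 0.84 in the nevi with a low ratio but -0.003 in the high-ratio nevi. Of 17 melanoma-associated genes 1 rose, CSPG4 (1.63), and 2 fell, among them MCAM (-1.92). Each count in this paragraph without a second value was the same adjusted over the list alone.

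No gene of the 4 keratinocyte lists fell past the threshold in nevi, and 1 of 11 basal keratinocyte genes rose (2 without the high-ratio nevi). Of 7 wound-type keratinocyte genes 5 rose (adjusted p = 0.709 with an estimated correlation), with S100A7 at 3.07, S100A8 at 2.79 and S100A9 at 2.39. Of 18 cornified envelope genes 3 rose, and 2 adjusted over the list alone (adjusted p = 0.9 with an estimated correlation), with the desmosomal cadherins DSG1 at 2.13 and DSC1 at 1.78, while 5 rose without the high-ratio nevi and 6 without nevus 3 and melanoma 14. Of 14 epithelial junction genes 3 rose, with a median of -0.02 and a mean of 0.35. Some of these calls ended when 1 normal skin array was left out, while the differences of the 3 S100 genes stayed above 2. S100A7 no longer passed without normal skin 1 (2.67), 4 (2.58), 5 (2.66) or 6 (2.79), S100A8 without normal skin 1 (2.43), 4 (2.43) or 5 (2.63), S100A9 without normal skin 1 (2.26), 2 (2.13), 4 (2.32) or 5 (2.11), and DSC1 without normal skin 1 (1.28) or 4 (1.43). S100A8 (1.61) also did not pass without probe sets ending in _x_at or _s_at, nor DSC1 with a pseudocount of 10 (1.84) or in a fit of only the 2 groups compared (1.78). The sweat gland list alone passed camera with an estimated correlation; 5 of the 36 lists had an unadjusted p under 0.05, and 13 passed with a preset correlation of 0.01.

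**Figure D2:**
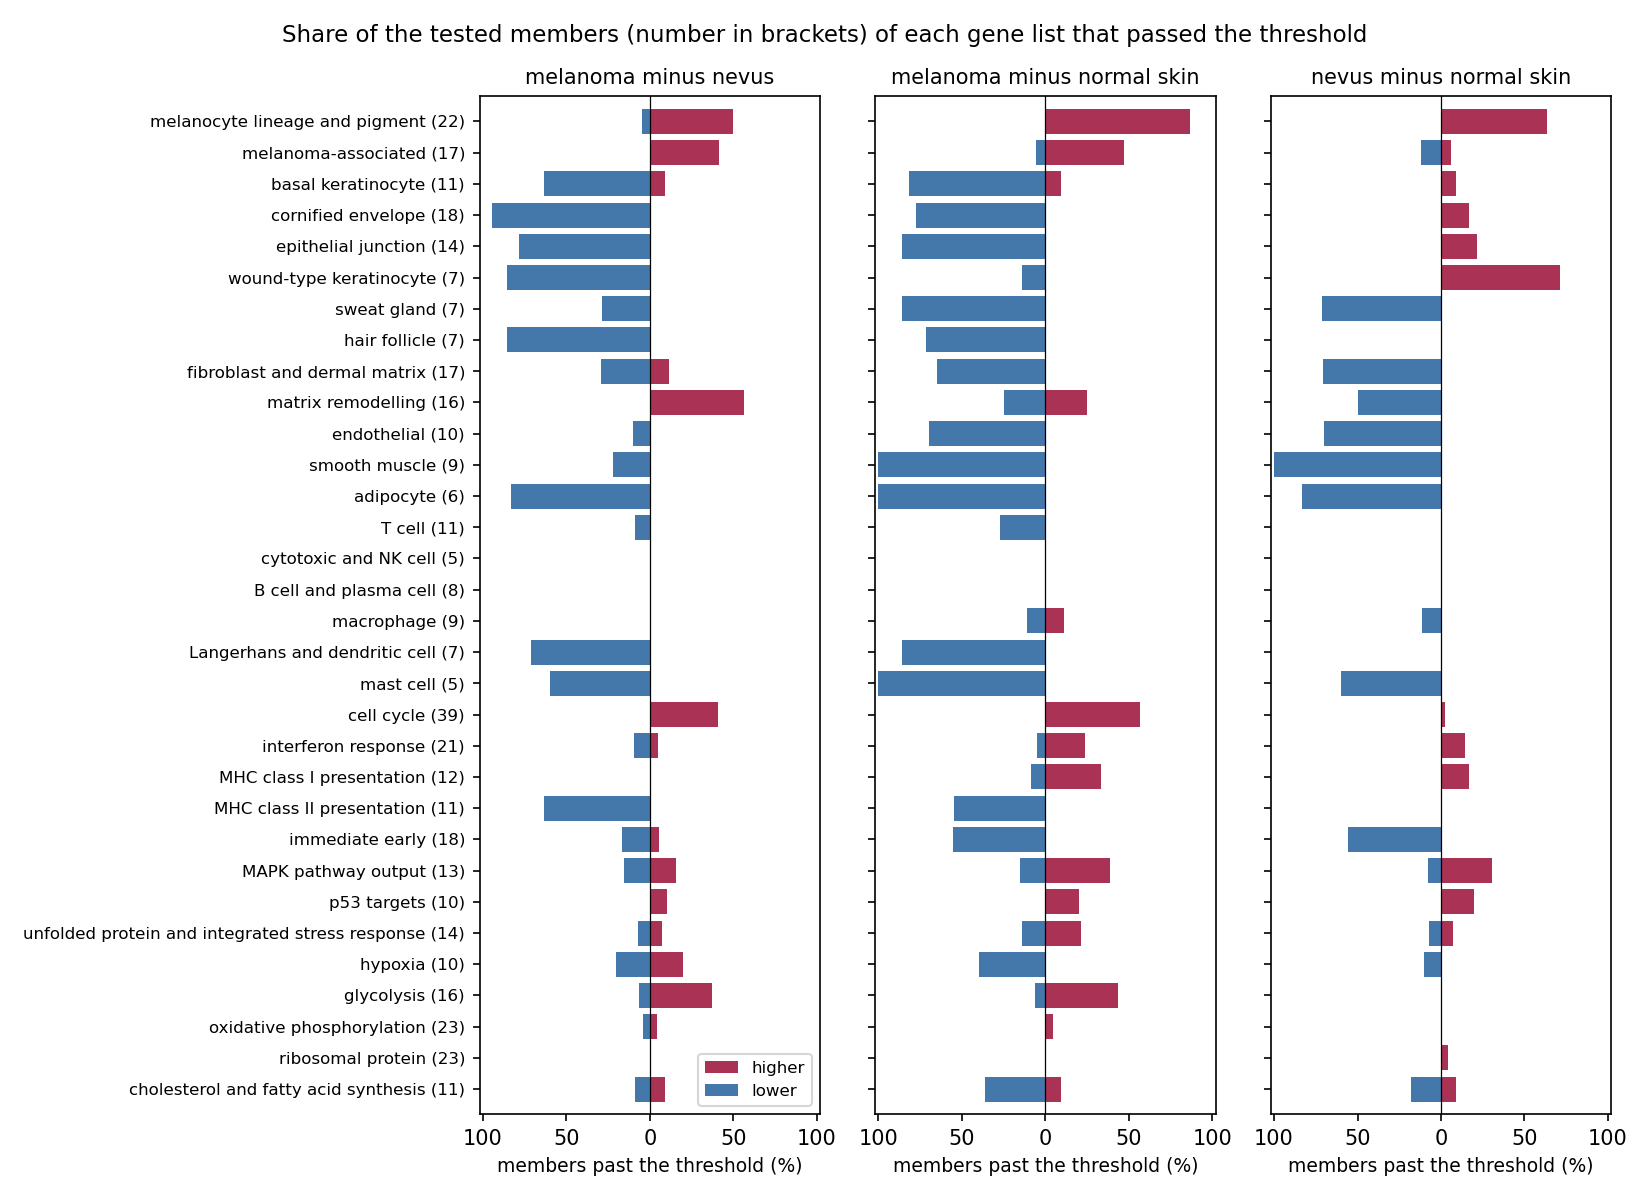
Share of the tested members of each gene list (in percent, number tested in brackets) that passed the threshold higher (red, to the right) or lower (blue, to the left) in each of the 3 comparisons, for the 32 lists with at least 5 tested members. Of 18 cornified envelope genes 17 were lower in melanoma than in nevi and none was lower in nevi than in normal skin, while all 9 smooth muscle genes were lower in both lesions than in normal skin.

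Whether more genes were higher or lower in nevi depended on the processing. More were higher with each array centred on its median (611 and 466 lower), a filter at the 75th percentile (416 and 372), the mean of the probe sets of a gene (521 and 464), and without normal skin 6 (588 and 584) or the 3 high-ratio nevi (737 and 717). With the 3'/5' ratio as a covariate 127 genes were higher and 360 lower, and the calls of PLXNB1 (0.94), GAPDHS (1.66), PMEL (1.82), DSG1 (0.79), DSC1 (1.23), S100A8 (3.67), S100A9 (2.37), DUSP4 (1.43) and CSPG4 (1.53) ended. With averaged arrays 40 genes were higher and 145 lower, and the calls of MLANA (3.46), TYR (2.52), PMEL (1.85), PLXNB1 (1.92), GAPDHS (1.98), S100A7 (2.5), S100A8 (2.69), S100A9 (2.39), DSG1 (1.18), DSC1 (0.74), FOSB (-2.74), DUSP1 (-2.06), ETV5 (1.86), DUSP4 (1.40), MCAM (-1.52) and CSPG4 (1.21) ended.

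The 3 high-ratio nevi alone, whose ratio lay within that of normal skin, had 58 genes higher and 126 lower than normal skin, against 730 and 715 for the other 15 nevi. The smaller counts follow in part from the smaller group, and S100A7, S100A8 and S100A9 lost their calls below with larger differences than in all 18 nevi. Among those 3 nevi SCGB2A2, SCGB1D2, MYH11, RBP4, LMOD1, G0S2, MLANA, TRPM1 and EIF2S3 still passed. These calls ended with those 3 nevi alone: TYR (2.60), TMEM259 (1.48), S100A7 (4.70), PLXNB1 (0.08), GAPDHS (1.26), PIP (-4.36), FABP4 (-3.67), PMEL (1.06), FBLN2 (-2.29), DSG1 (0.75), DSC1 (1.17), S100A8 (4.11), S100A9 (2.62), ETV5 (1.79), DUSP4 (0.31), MCAM (-1.18) and CSPG4 (0.85).

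Genes past the threshold against both benign groups come closest to the question of the series title, but some of them were also raised or lowered in nevi. In melanomas 393 genes were higher than in both nevi and normal skin, led by GDF15 (smaller difference 4.47), PHACTR1 (3.92), NES (3.44), SPP1 (3.29), ABHD2 (3.14), NTRK3 (3.06), L1CAM (3.04), UBE2S (2.99), DUSP4 (2.99) and GPR143 (2.98). Of these 393 genes 312 did not pass in nevi against normal skin. Of the leaders at least GPR143 and DUSP4 also rose in nevi against normal skin, so their rise is not particular to melanoma. ABHD2 and UBE2S differed more from normal skin than from nevi, so their means in nevi lay above those in normal skin. Their rise may not be particular to melanoma either. In melanomas 629 genes were lower than in both benign groups, 511 of which did not pass in nevi against normal skin, led by KRT14 (-6.90, the difference nearer to 0), KRT15 (-6.31), LORICRIN (-6.08), KRT5 (-5.91), KRT1 (-5.54), AQP3 (-5.46), FGFR3 (-5.44), DSP (-5.32), HOPX (-5.21) and SERPINB5 (-5.09). Every melanoma lay above every benign sample for 3 genes, PKM, CNIH3 and MYO1D, and below every benign sample for 3, ABLIM1, BAG1 and KLHDC2, all but PKM named after their values were seen. A gene with no difference would do so in a share of 3.1e-19 of splits, if all 70 arrays were independent, which the labels do not say. These genes were also picked from 9092 by their separation, so the share is no test of them. Both comparisons share the melanoma arrays, and independent lists of the same lengths would share 57.7 and 115 genes. In 100 simulations with no differences the highest count was 0 for each direction. These hold no real differences, so they cannot show how much the shared arrays add to lists of genes that do differ. With the melanomas split into 22 and 23 arrays, 1 part for each benign group, 395 and 622 genes were shared. The covariance of the paired differences was 0.68, against 0.006 in the simulations. With the keratinocyte score as a covariate 246 genes were higher and 203 lower than in both benign groups, of which 203 and 183 were among those first called. With averaged arrays 281 genes were higher and 401 lower than in both benign groups, of which 170 and 311 were among those first called. The calls of ABHD2 against nevi (1.32), of L1CAM against nevi (1.18) and normal skin (1.08), and of NTRK3 against nevi (0.52) and normal skin (0.09) then ended.

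In both lesions 364 genes were higher than in normal skin, led by MLANA (smaller difference 4.29), TYR (3.26), MAD1L1 (2.94), PMEL (2.89), TMEM259 (2.87), CRIP2 (2.87), TRPM1 (2.85), GPR143 (2.85), SDC3 (2.82) and PSMC3 (2.63). In the high-ratio nevi minus the other nevi MAD1L1, CRIP2 and PSMC3 had log2 differences of -3.09, -4.69 and -4.33, GPR143, PMEL, SDC3 and TMEM259 of -1.82, -2.20, -2.28 and -2.02, and TYR, TRPM1 and MLANA of -0.80, -0.46 and -0.33. In both lesions 454 genes were lower, led by the sweat gland genes SCGB2A2 (-7.47), SCGB1D2 (-7.11) and PIP (-5.69), then FABP4 (-5.18), MYH11 (-4.78), RBP4 (-3.71), LMOD1 (-3.60), KRT19 (-3.60), PLIN1 (-3.50) and SCGB2A1 (-3.47). Both comparisons share the 7 normal skin arrays. Independent lists would share 57.9 and 82.8 genes, the highest counts in 100 simulations with no differences were 28 and 134, and with the normal skin arrays split into 3 and 4 the counts were 130 and 238. The split also leaves fewer normal skin arrays in each fit, which can lower the counts by itself. It therefore does not measure how much the shared arrays add. The correlation of the paired differences was 0.68, against 0.80 in the simulations, and the covariance 0.53 against 0.05. More shared genes were higher than lower with each array centred on its median (455 and 368) and with a filter at the 75th percentile (312 and 302). With the 3'/5' ratio as a covariate 88 and 295 genes were shared, and in nevi against normal skin CRIP2 (-0.16) and PSMC3 (-0.18) turned and GPR143 (2.22) no longer passed. With averaged arrays 30 and 129 genes were shared, and in nevi MAD1L1 (2.04), CRIP2 (1.94), GPR143 (1.97) and PSMC3 (1.78) no longer passed. In the 3 high-ratio nevi alone MAD1L1 (0.36), SDC3 (0.92) and GPR143 (1.33) did not pass, and CRIP2 (-1.04) and PSMC3 (-0.98) lay below normal skin.

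**Figure D3:**
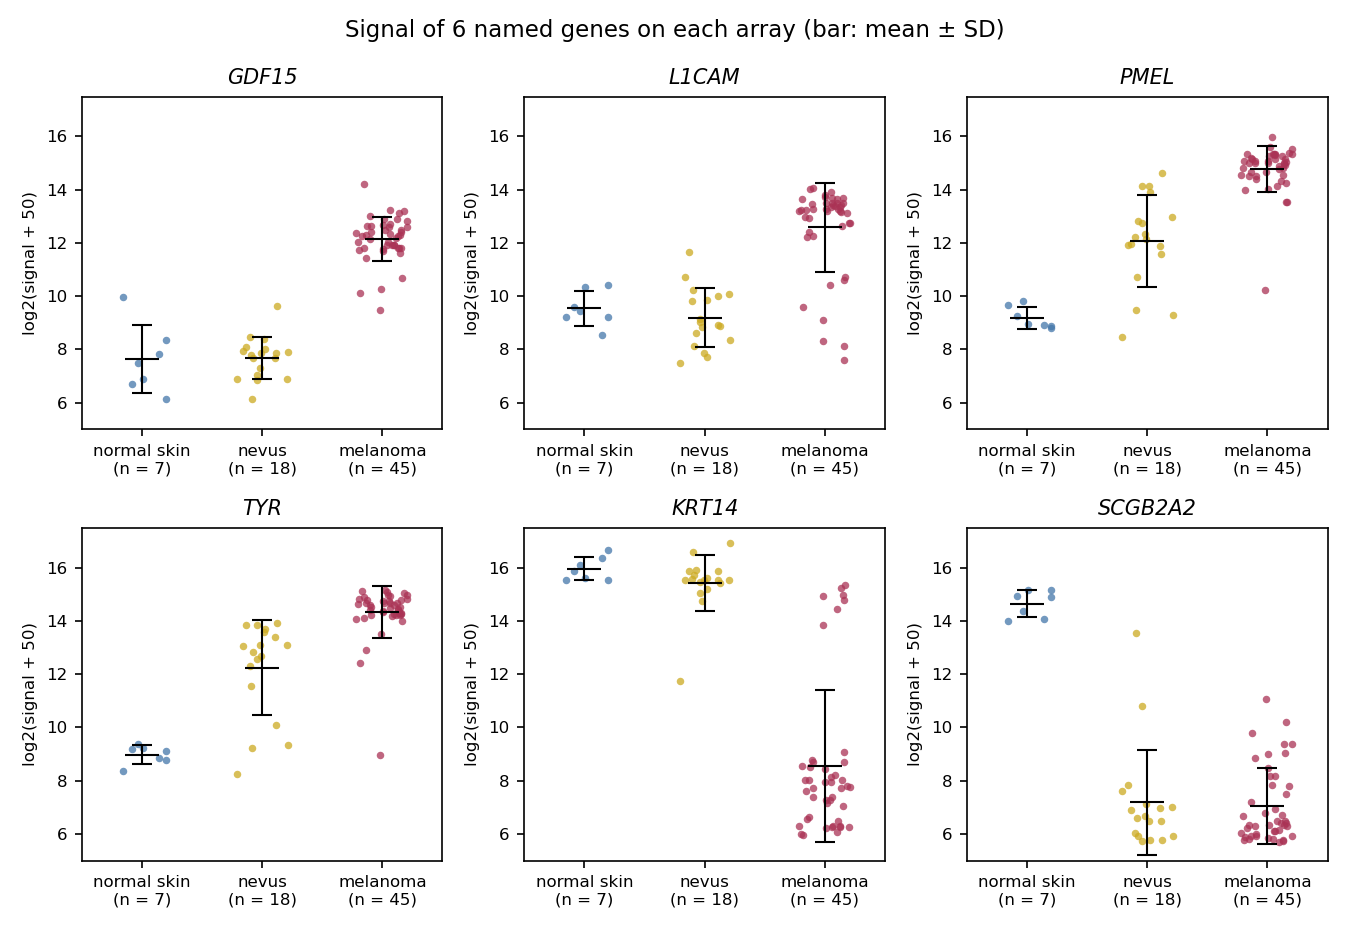
Log2 of the deposited signal plus 50 (y axis) of GDF15, L1CAM, PMEL, TYR, KRT14 and SCGB2A2 on each array (points) of normal skin (n = 7), nevi (n = 18) and melanomas (n = 45), with the mean and SD of each group (bars). GDF15 is at 12.16 in melanomas against 7.69 in nevi, KRT14 at 8.54 against 15.44, and SCGB2A2 is at 14.65 in normal skin against 7.18 in nevi.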

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

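The random splits were set before their results were seen, and every other test in this part was chosen after its result, or values it can be worked out from, had been seen.

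Genes of sweat glands, fat, smooth muscle and vessels were lower in nevi than in normal skin, while normal skin also had the higher 3'/5' ratio. Shortened RNA in normal skin is argued against as the whole cause for sweat gland and smooth muscle genes, whose medians in the 3 high-ratio nevi minus normal skin were -3.12 and -3.38 (SD over the 3 nevi 1.52 and 1.20). It stays open for adipocyte genes (-2.98, SD 2.17), as the 3 nevi were few and differed. It stays open for endothelial genes (-1.17, SD 0.42) as well. Their medians in the 3 nevi were -1.27, -1.08 and -1.89, but the fall did not exceed 1 by more than its SD, the limit set for all 4 lists. In nevus 15 the sweat gland, smooth muscle, adipocyte and endothelial medians were -1.16, -1.95, -0.36 and -1.08. A dilution of all other cell types alike by melanocytes is argued against as the whole cause by the cornified envelope list. Its median was 1.02 (SD over members 0.65, SE over arrays 0.56), against -1.53 (SD 1.16, SE 0.20) for the highest of the 4 lists. The argument rests on the gap between the lists, as with this SE it stays open whether the cornified list rose at all. The basal keratinocyte median was -0.44 (SD 0.85), so a part in the fall, or more cornified cells in the nevus samples, stays open. Whether the normal skin samples held more of the deeper skin layers stays open: 84.4% of the 32 tested members were lower in nevi by 0.5 or more, but this restates the pattern and decides nothing, and the labels do not say how samples were taken.

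Keratinocyte genes were lower in melanoma than in nevi. RNA quality of the nevi is argued against: in melanomas minus the 15 nevi with a low ratio, all 43 tested members had a median of -3.38 (SE 0.29). A larger share of tumour cells that lowers all other cell types alike is argued against as the whole cause: among genes far enough above the floor in nevi to show a like fall, the 40 keratinocyte genes had a median of -3.40 (SD over members 2.05), but 7 macrophage genes one of 0.64 (SD 0.47) and 4 endothelial genes one of 0.35 (SD 0.25). These were the highest medians of 7 lists with at least 3 such genes. A list was called apart when its median less its SD stayed above both a fall of 1 and the keratinocyte median plus its SD. By this rule 4 of the 7 lay apart from the keratinocyte fall. The T cell list (-0.88, SD 0.38) missed only the limit of 1. The mast cell (-1.31) and Langerhans and dendritic cell (-1.71) lists met neither part. The SDs are over genes of a list, which are not independent, and not over samples. A part in the fall stays open, since 15 of 45 such genes of other cell types were lower by 1 or more, all 3 mast cell genes and 2 of 2 adipocyte genes among them, and macrophages or vessels that rose were not excluded. Less epidermis in the melanoma samples stays open too, as the Langerhans and dendritic cell median was -1.19 but mast cells (-1.30) and adipocytes (-1.26), which lie outside the epidermis, had like medians, and a change of keratinocyte expression within the lesions was not tested.

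Of the 45 melanoma arrays 35 joined a group of like arrays, while the largest such group of nevi had 6 of 18. RNA quality stays open: 6 of the other 10 melanomas had a ratio within the range of the 35 and 4 lay below it, which decides nothing. Samples that share tissue, such as several pieces of a tumour, stay open too: the median correlation of pairs of the 35 was 0.934, in part by how they were picked, and without repeat arrays of a sample in the series this cannot be told apart from alike tumours. A test of tumour-cell share that compared the 35 with the other 10 was also run and then dropped after its result was seen, because groups drawn from the data must not be compared on the same data. No biological explanation was tested, since the labels give no subgroup of melanomas.

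Chance was tested for each count by splitting the arrays at random into groups of the same sizes, with 100 splits including the real one, which alone gave a count as large in each case (1 of 100). The real counts and the highest of the other splits were 1276 and 15 for melanoma against nevus, 2399 and 857 for melanoma against normal skin, and 1061 and 408 for nevus against normal skin. For the shared counts they were 393 and 0, 629 and 0, 364 and 8, and 454 and 0. Splits of other sizes that follow the 3'/5' ratio, drawn after it was seen, gave 1443 genes for 15 nevi with a low ratio against 7 normal skin arrays and the 3 high-ratio nevi, and 1818 for the 15 against the 3 nevi. The sizes and the arrays that set the spread differ from those of the real groups, so these counts give no exact measure against 1061. The 1818 genes came from fewer arrays than the 1061, but no random splits of 15 against 3 arrays were run. How much the small group of 3 adds to this count is therefore not known. Nevi that differed in the ratio had many genes past the threshold within 1 label, and RNA quality was not parted from other traits of the 3 nevi. With the ratio as a covariate nevus against normal skin had 127 genes higher and 360 lower.

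Of 140 measures tested in the 7 normal skin arrays, 13 had an array far from the others by the gap test of Dixon, where chance gives about 7. ATP6V0E2 was at 8.49 in normal skin 3 (others 10.05 to 10.60), BCL2A1 at 8.06 in normal skin 2 (6.84 to 7.35) and ENO2 at 7.25 in normal skin 2 (8.65 to 9.52). EPHA4 was at 8.07 in normal skin 1 (6.29 to 6.74) and PHACTR1 at 7.37 in normal skin 7 (5.80 to 6.37). In normal skin 6, DCN was at 15.14 (13.43 to 13.96), GAPDHS at 8.09 (6.32 to 6.98), MAD1L1 at 8.19 (5.83 to 5.99), MCAM at 11.06 (11.73 to 12.05), the log2 3'/5' ratio of ACTB at 3.14 (5.40 to 7.08) and the mast cell score at 2.70 (0.48 to 1.27). Normal skin 5 had a median signal of 344.6 (256.9 to 281.2) and 64.9% of probe sets above a signal of 200 (56.4 to 59.2).

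Among probe sets outside the gene tests, 81 of 741 with several symbols passed between melanoma and nevus, 23 higher and 58 lower. Of 1019 without a symbol 109 passed, 36 higher and 73 lower.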

How the results depend on the processing

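The fits of averaged arrays, of the 3 high-ratio nevi alone, without the 3 high-ratio nevi and without nevus 3 and melanoma 14 were chosen after the result was seen. Counts are given as melanoma against nevus, melanoma against normal skin, nevus against normal skin (each higher and lower), then the 4 shared counts in the order higher in melanoma than both, lower in melanoma than both, higher in both lesions, lower in both lesions. Of 227 count values under alternatives 178 stayed within 1.5 times and 49 moved. Of 2995 values of 148 named differences 2873 kept their side of the threshold, 111 kept direction only, and 11 reversed with the gene past the threshold in either fit. A change of sign where the gene passed in neither fit was not counted as a reversal and is among the 2873. Of 3744 list counts 495 moved.

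A pseudocount of 200 gave 323 and 486 against nevi, 291 and 351 for nevi, and shared counts of 257, 359, 199 and 292. With a filter at the 75th percentile, which tests fewer genes, the last shared count was 302. Without probe sets ending in _x_at or _s_at, again with fewer genes, the values were 326 and 496, 590 and 897, 285 and 362, then 246, 416, 203 and 292. With no limit on size they were 2583 and 2573, 2362 and 3201, 1348 and 1893, then 1645, 1942, 1053 and 1457, as a looser rule must give. With the keratinocyte score as a covariate melanoma against nevus had 301 and 266, and the shared counts were 246 and 203 for melanoma. With the 3'/5' ratio as a covariate nevus against normal skin had 127 and 360, of which 73 and 282 were among the genes first called, and the counts of both lesions were 88 and 295. Averaged arrays, with 10, 8 and 6 samples, gave 323 and 488 against nevi, 40 and 145 for nevi, and shared counts of 401, 30 and 129 for the last 3. The 3 high-ratio nevi alone gave 58 and 126. With the preset correlation of 0.01, lists past the set test went from 0 to 14, 0 to 16 and 1 to 13. For the other alternatives the cause was not tested.

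Directions reversed for S100A7 (1.14), S100A8 (0.93), IFI27 (0.0505) and ISG15 (-0.0268) in melanoma against nevus with the keratinocyte score. They reversed for PSMB8 in melanoma against normal skin (-0.62) and for CRIP2 (-0.16) and PSMC3 (-0.18) in nevus against normal skin with the 3'/5' ratio. Among the 3 high-ratio nevi CRIP2 was at -1.04 and PSMC3 at -0.98, and with averaged arrays HLA-DPA1 was at 0.0241 and HLA-DRB1 at 0.42 against nevi. In each case the cause was not tested. Without each normal skin array in turn, counts ranged from 983 to 1078 and 1331 to 1390 for melanoma, 447 to 588 and 530 to 597 for nevi, and 388 to 399, 601 to 627, 320 to 424 and 427 to 496 for the shared counts, and none moved. Signals near the background, which the added 50 flattens, limit what could be seen of genes of low signal. No paired analysis was possible because replicate numbers follow the order of deposit only.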

Other observations

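The fits of averaged arrays, without the 3 high-ratio nevi and without nevus 3 and melanoma 14 and the naming of PRAME were chosen after the result was seen; the lists, chromosome sets and pairs of scores were planned, with the scores over all 45 melanomas and not the 35 used here.

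In melanoma against nevi 1 of 11 T cell genes fell, and none of 5 cytotoxic and NK cell, 8 B cell and plasma cell or 9 macrophage genes passed. Of 5 mast cell genes 3 fell (adjusted p = 0.552 with an estimated correlation), and the only red blood cell gene tested, HBB, fell by 1.21. Of 21 interferon response genes ISG15 rose (1.12) and IFI27 (-2.05) and GBP2 (-1.43) fell, and none of 12 MHC class I genes passed. The ISG15 difference was 0.99 without the 3 high-ratio nevi and 0.97 with a pseudocount of 200, both under the limit, and with averaged arrays the calls of ISG15 (0.35) and IFI27 (-0.17) ended. With the keratinocyte score as a covariate GBP2 (-0.85) no longer passed, and ISG15 (-0.03) and IFI27 (0.05) reversed. Of 10 endothelial genes 1 fell, of 9 smooth muscle genes 2, of 6 adipocyte genes 5 (adjusted p = 0.473 with an estimated correlation; 3 without the high-ratio nevi), and of 7 sweat gland genes 2. Of 18 immediate early genes KLF4 (-3.42) and 2 others fell and 1 rose. Of 13 genes of MAPK pathway output 2 rose, with DUSP4 at 2.99, and 2 fell, with the receptor EPHA4 at -2.10. Without the high-ratio nevi 1 MAPK gene rose, 1 smooth muscle gene and 2 T cell genes fell, and 2 immediate early genes rose and 4 fell. Of 10 p53 targets BAX rose (1.32; 0.98 without the high-ratio nevi, 0.86 with a pseudocount of 200 and 0.94 with the keratinocyte score). Of 14 unfolded protein and integrated stress genes 1 rose and 1 fell, of 10 hypoxia genes 2 and 2, of 23 oxidative phosphorylation genes 1 and 1, with COX5A at 1.88, and of 11 cholesterol and fatty acid genes 1 and 1, with SCD at 1.99. With averaged arrays COX5A (0.63) and SCD (1.13) no longer passed. None of 23 ribosomal protein genes passed, with a list median of -0.61 (adjusted p = 0.287 with an estimated correlation), and none of 3 skeletal muscle, 2 Schwann cell or 2 cancer-testis genes did.

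Against normal skin, the lists not yet described gave these counts in melanoma. Of 11 T cell genes 3 fell, of 9 macrophage genes 1 rose and 1 fell, and none of 5 cytotoxic and NK cell or 8 B cell and plasma cell genes passed. Of 21 interferon response genes 5 rose and 1 fell, and with the 3'/5' ratio as a covariate 1 rose and 2 fell. Of 16 matrix remodelling genes 4 rose and 4 fell, of 7 hair follicle genes 5 fell, and of 7 wound-type keratinocyte genes 1 fell, or 0 adjusted over the list alone. Of 10 p53 targets 2 rose, of 14 unfolded protein genes 3 rose and 2 fell, of 10 hypoxia genes 4 fell, of 23 oxidative phosphorylation genes 1 rose, and of 11 cholesterol and fatty acid genes 1 rose and 4 fell. None of 23 ribosomal protein genes passed (adjusted p = 0.651 with an estimated correlation). Of 2 Schwann cell genes 1 rose, of 3 skeletal muscle genes 1 fell, the red blood cell gene fell, and none of 2 cancer-testis genes passed. In nevi against normal skin 3 of 21 interferon response genes rose, or 1 adjusted over the list alone (adjusted p = 0.919 with an estimated correlation), as did 2 of 12 MHC class I genes, 1 of 39 cell cycle genes (adjusted p = 0.9 with an estimated correlation), 2 of 10 p53 targets and 1 of 23 ribosomal protein genes. Of 5 mast cell genes 3 fell, of 9 macrophage genes 1, of 10 hypoxia genes 1 and of 3 skeletal muscle genes 1. Of 14 unfolded protein genes 1 rose and 1 fell, and of 11 cholesterol and fatty acid genes 1 rose and 2 fell. In the hair follicle, T cell, cytotoxic and NK cell, B cell and plasma cell, Langerhans and dendritic cell, red blood cell, Schwann cell, cancer-testis, MHC class II, glycolysis and oxidative phosphorylation lists none passed. Without the high-ratio nevi 2 hair follicle genes fell, 2 glycolysis genes and 1 macrophage gene rose, and 3 ribosomal protein, 2 melanoma-associated, 2 unfolded protein and 2 cholesterol and fatty acid genes rose. Without nevus 3 and melanoma 14 no ribosomal protein gene rose, and 1 B cell and plasma cell gene and 2 macrophage genes fell.

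The median, mean and test of a list differed in sign for the fibroblast, endothelial, hypoxia and interferon lists in melanoma against nevus, for matrix remodelling, B cell and macrophage lists in melanoma against normal skin, and for the basal keratinocyte, junction, Schwann cell, T cell, B cell, unfolded protein, oxidative phosphorylation, glycolysis and ribosomal lists in nevus against normal skin. No autosome passed as a set in camera in any comparison, with the smallest adjusted p at 0.312 for chromosome 9 in melanoma against nevus. Across genes, which are not independent replicates, the difference of high-ratio minus other nevi had r = -0.51 with melanoma minus normal skin. Of the 2399 genes called between melanoma and normal skin 78.9% had the opposite sign in high-ratio minus other nevi, against 67.5% of all other genes.

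As melanomas fell into a group of 35 like arrays and 10 others, scores were correlated over the 35 only, in 8 pairs with 100000 permutations and adjusted over the 8. Hypoxia and glycolysis scores rose together, with Pearson r = 0.70 (permutation p = 1e-05, the smallest they can give, adjusted p = 8e-05), Spearman rho = 0.61 (permutation p = 0.00012, adjusted p = 0.00096) and r = 0.60 without the 2 samples farthest from the median of the first score. Cell cycle and pigment scores had r = 0.54 (permutation p = 0.00056, adjusted p = 0.00224) but rho = 0.39 (permutation p = 0.0221, adjusted p = 0.0884) and r = 0.36 without those 2. T cell and MHC class II scores had r = 0.39 (permutation p = 0.019, adjusted p = 0.0507), rho = 0.33 (permutation p = 0.0528, adjusted p = 0.141) and r = 0.11 without those 2, so the relation rests on them. The other 5 pairs did not pass: cornified envelope with pigment (r = -0.002, rho = 0.03) and with cell cycle (r = 0.20, rho = 0.11), T cell with interferon response (r = -0.16, rho = -0.18) and with cell cycle (r = 0.20, rho = 0.26), and immediate early with the GAPDH 3'/5' ratio (r = -0.25, rho = -0.16). Their permutation p for r were 0.989, 0.258, 0.363, 0.250 and 0.150, and for rho 0.870, 0.528, 0.289, 0.127 and 0.347.

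PRAME, a tumour antigen named after its values were seen, lay above every benign sample in 8 of the 45 melanomas.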
